A study of Homo sapiens with 93 samples.

How the data were processed

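The measurements were RNA-seq of MCF7 cells, as 8 bulk libraries and 85 single-cell libraries, at 0, 3, 6 and 12 h of estradiol. Per the labels, cells spent 3 days in charcoal-stripped medium without phenol red, and libraries of polyadenylated RNA were made with Nextera XT. The deposited values are FPKM, 1 value per gene and library, not rounded to whole numbers. The authors aligned reads with TopHat2 2.0.6 to the human genome build hg19, and the program and annotation behind the FPKM are not given in the sources used here. The table held 57424 entries and 93 library columns, all used. Of the entries, 49 for the pseudoautosomal copies on the Y chromosome were left out, 33 of them identical to their X copy, which left 57375. Gene classes came from GENCODE release 29 by gene identifier without version, which gave a class to 51804 entries, and 226 symbols stood for more than 1 entry.

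Groups were the times in the labels. At each time 1 bulk library is labelled 10k and 1 is labelled 100k, called replicates 1 and 2 here. The labels do not explain them. Bulk values were analysed as log2(FPKM + 1), over the 13136 genes with a mean FPKM of at least 1 over the 8 libraries, with limma 3.58.1 in R 4.3.3 (a linear model with a mean per time, contrasts, and eBayes with trend). The fit had 4 residual degrees of freedom and a median prior of 3.3. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05, and tests were two-sided. A fold change on this scale understates the change of genes with low values. The comparisons 3, 6 and 12 h against 0 h, 12 against 6 h and the test of any effect of time were chosen before the data were examined, as were the gene lists, the rule for named genes and the alternatives not said to be added. Those against 0 h share the 0 h libraries. Comparisons of 12 and 6 h against 3 h and, in cells, of 12 against 6 h were added afterwards.

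The rule for named genes took, in each comparison, genes with an adjusted p under 0.05, a mean FPKM of at least 5 in the higher time and no overlap between the libraries of both times, and of these the 8 largest rises and 8 largest falls. It was repeated without small RNA genes after the data were examined. TFF1, GREB1, PGR, MYC, CCND1, ESR1, SHMT2, MTHFD2, MTHFD1L, ODC1, AMD1, SRM, PPAT, PAICS, GART and ATIC were always named, and up to 4 members of a list with the largest change. SLC3A2, AREG, RERG, HSP90AB1, DNAJA1, FOS and other list members outside these ranks were named after their values were seen. One locus that the rule named at 6 h is left out because its name reads as a number. For genes listed at 0 in every library of a time no fold against 0 h is given, and their fitted values between later times are given as no measure of size.

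There were 25 gene lists, and the 23 with at least 3 tested members were tested in bulk with camera of limma (preset correlation 0.01, and again with a correlation estimated per list), with adjustment over lists within a comparison. With the preset, camera p-values rest on the number of genes, and with an estimate on the 4 residual degrees of freedom. The estimate was below the preset 0.01 for some lists, so a call that ended with it does not by itself show correlated members. The number of members past the threshold was also adjusted over the list alone. Fry of limma, planned as well, tested whether the members of a list changed in a shared direction, without comparison with other genes. Its values are given only for the lists of the series title.

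In cells, each time was 1 sample, and no p-value, standard error or count of changed genes was computed from cells. The mean and median FPKM, the share of cells at an FPKM of at least 1 with its exact (Clopper-Pearson) 95% interval, and the log2 ratio of means after adding 1 were computed. A list's median was placed among 10000 random lists of equal size matched on mean level. These draw genes independently, so a list whose members move together reaches an extreme percentile more easily. A percentile is thus a description and no test between times. By the size rule, genes with a mean FPKM of at least 10 at one of 0 and 12 h and an FPKM of at least 1 in at least 50% of the cells of that time were ranked by fold, and the 8 largest each way were named. Of all genes 6084 qualified. Cells were processed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

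Alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, quantile normalization, median ratio scaling, no trend, the 10k or 100k label as a replicate block, only the libraries of the times compared, and leaving out each library. In cells they were a pseudocount of 0.1, the mean of log2 values, cells scaled to an equal total and a detection level of 5. A fit without small RNA genes and one with the prefix of the library name as a covariate were added afterwards. The fit was tested on simulated data of the same size, in which 2 of 60 genes changed by 0.5 on the log2 scale, 16 of 70 changed by 1 and 50 of 70 changed by 2 were called, beside 5 false calls.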

Results

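MCF7 is an estrogen receptor-positive human breast cancer cell line. Its RNA was sequenced from pooled (bulk) cells and from single cells before estradiol (0 h) and after 3, 6 and 12 h with it. The bulk set held 2 libraries per time, 8 in all, 1 labelled 10k and 1 labelled 100k at each time. The single-cell set held 21 cells at 0 h, 21 at 3 h, 19 at 6 h and 24 at 12 h, 85 in all. Values were the deposited FPKM (fragments, scaled for transcript length and library size). Such values carry no read counts, so the depth is unknown. Bulk libraries held 12492 to 13077 genes at an FPKM of 1 or more, and cells held a median of 7796 genes at 0 h, 7386 at 3 h, 7614 at 6 h and 8057.5 at 12 h. The labels do not say that the 2 libraries of a time came from separate cultures. Limma p-values thus measure only the spread between these libraries, which may be technical. Camera p-values with the preset correlation set the genes of a list against other genes, so their size does not measure that spread. The protocol states that cells of 0 and 3 h were stained with a green dye and cells of 6 and 12 h with an orange one, 24 h before treatment. It names ethanol as the vehicle, but no vehicle library is labelled for 3, 6 or 12 h.

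The first comparison asked what had changed in bulk after 3 h with estradiol. CYP1A1, a cytochrome P450 that metabolises xenobiotics and estrogens, rose from an FPKM of 4.73 ± 2.85 (SD, n = 2) to 293 ± 108 (SD, n = 2), a log2 fold change of 5.72 (SE 0.37). CYP1B1, a related enzyme, rose from 30.3 ± 0.794 to 151 ± 0.0481, and TIPARP, another known target of the aryl hydrocarbon receptor, rose by 2.36 on the log2 scale. SLC7A5, the light chain of a large neutral amino acid transporter, rose from 6.55 ± 0.338 to 38.3 ± 0.0183, and CYP24A1, which inactivates vitamin D, rose by 2.43. Among genes that fell, the potassium channel gene KCNJ8 changed by -2.42, the surface antigen gene PSCA by -2.12 and the antiproliferative gene BTG2 by -1.86. TMEM139 changed by -1.79 and the pseudogene CMAHP by -1.80. The rule for named genes also gave 4 small RNA genes, SNORD14A, Y_RNA, SNORA27 and RNU1-70P, with means of 812, 118, 64.9 and 14.2 at 3 h and values of 0 or next to it at 0 h. Of its less known loci, AC026407.1 was listed at 0 in both 0 h libraries and AP000758.1 in both 3 h libraries, AC018865.8 rose by 2.64 and RP11-328M4.2 by 2.63, while RP11-252P18.1 changed by -3.41 and RP11-112J1.1 by -2.69. Of the 8 fits without 1 library, the calls of CYP24A1, TMEM139, CMAHP and RP11-328M4.2 ended in 8, of BTG2, RP11-252P18.1 and RP11-112J1.1 in 6, of TIPARP in 5, of PSCA and AC018865.8 in 4 and of KCNJ8 in 2, without a change of direction, while those of CYP1A1, CYP1B1 and SLC7A5 held in each.

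Of 30 tested members of the MYC-linked ribosome biogenesis list, 13 rose and none fell at 3 h, and 21 rose when adjusted over the list alone. RRP12 rose by 1.24, NIP7 and DDX21 by 1.17 and NOP56 by 1.05 (camera adjusted p = 7.38e-20 for the list, and adjusted p = 0.00974 with an estimated correlation). Estrogen-induced targets had 4 of 35 members higher and none lower, 11 when adjusted over the list alone. These were AREG (1.01), GREB1 (0.80), HSPB8 (0.73) and TPD52L1 (0.50), with a camera adjusted p of 1.42e-06 and an adjusted p of 0.0302 with an estimated correlation. Estrogen-repressed targets had 5 of 17 lower, among them TP53INP1 (-1.54), EFNA1 (-1.32) and PNRC1 (-1.32), while CYP1A1, which is also on that list, was its 1 riser. When adjusted over the list alone, 10 were lower and 1 higher (camera adjusted p = 2.61e-09, and adjusted p = 0.0276 with an estimated correlation). The aryl hydrocarbon receptor list had 3 of 5 members higher by either adjustment (camera adjusted p = 2.14e-05). This call ended in the camera fit with an estimated correlation (adjusted p = 0.0546), although the estimate, -0.084, was below the preset. In all, 256 of 13136 tested genes passed at 3 h by limma with Benjamini-Hochberg adjustment (adjusted p under 0.05), 186 higher and 70 lower. Leaving out any 1 of the 8 libraries lowered this count, to between 45 and 107, with 41 higher and 39 lower without replicate 1 of 0 h and 33 and 32 without replicate 2. The count was 4 when the 4 libraries of 0 and 3 h were fitted alone.

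**Figure D1:**
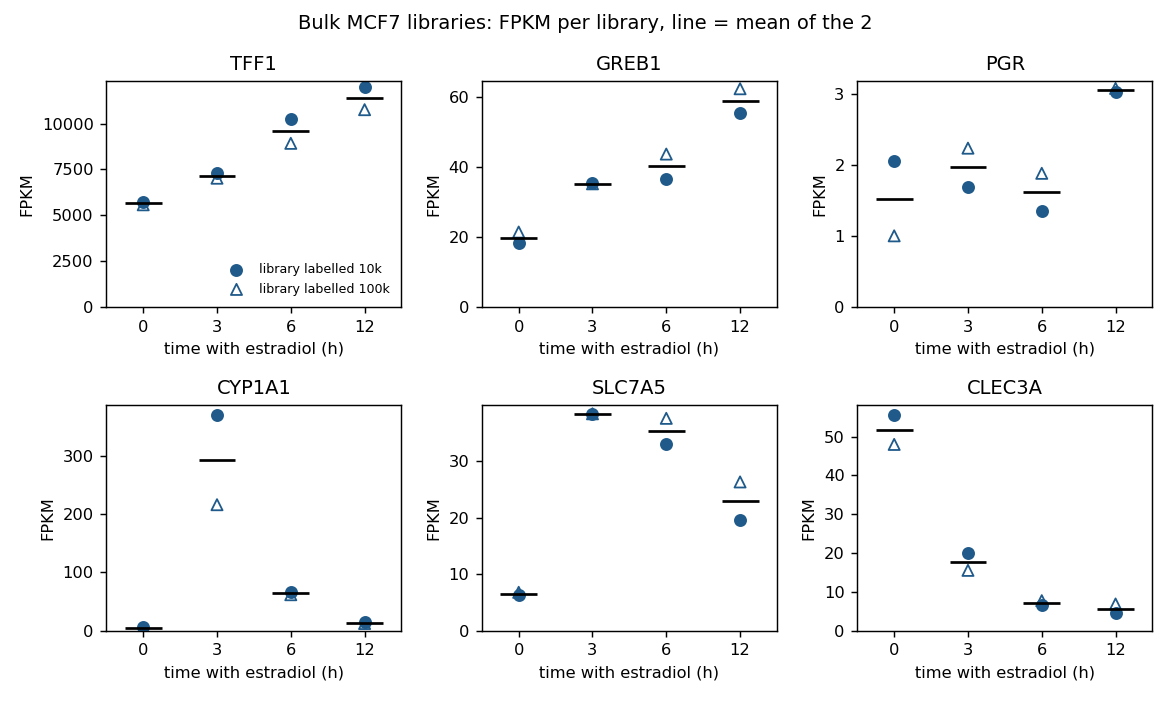
FPKM of 6 genes in each of the 8 bulk libraries (vertical axis, linear from 0) against hours with estradiol (horizontal axis). Filled circles are libraries labelled 10k, open triangles libraries labelled 100k and lines the mean of both. CYP1A1 and SLC7A5 are highest at 3 h, with means of 293 and 38.3, TFF1 and GREB1 are highest at 12 h, with means of 11380 and 58.8, and CLEC3A has its highest mean, 51.8, at 0 h.

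After 6 h, FABP5, a fatty acid-binding protein gene, had risen from an FPKM of 8.01 ± 2.14 (SD, n = 2) to 51.2 ± 3.66 (SD, n = 2), a log2 fold change of 2.55 (SE 0.18). SLC7A5 was higher by 2.26, with its heavy chain partner SLC3A2 higher by 1.45, C8orf46 by 1.77 and PTGES, a prostaglandin E synthase gene, by 1.73. CLEC3A, a C-type lectin gene, fell from 51.8 ± 5.41 to 7.14 ± 0.871, and CTGF, a matrix-associated growth factor gene, fell from 41.2 ± 9.55 to 6.995 ± 1.11. KLHL24 changed by -2.55 and YPEL3 by -2.40, both members of the estrogen-repressed list. CYP1A1, at 64.0 ± 3.00, was still above 0 h by 3.6. RNU6-450P, SNORA45, RNU1-70P, RP11-162J8.3 and AC026407.1 were listed at 0 in both 0 h libraries and AP000758.1 in both 6 h libraries. C14orf182 rose by 1.73, while RP11-112J1.1 changed by -2.48 and CTB-167G5.5 by -2.38. Without 1 library the calls of FABP5 and SLC7A5 held in each of the 8 fits, while those of PTGES ended in 8, of C14orf182 in 7, of RP11-112J1.1 in 6, of KLHL24, YPEL3 and CTB-167G5.5 in 5, of SLC3A2, C8orf46 and CTGF in 4, of CYP1A1 in 2 and of CLEC3A in 1.

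Estrogen-repressed targets had 10 of 17 members lower and CYP1A1 higher at 6 h, 14 lower and 1 higher when adjusted over the list alone (camera adjusted p = 8.83e-13, and adjusted p = 0.0148 with an estimated correlation). ESR1, which encodes the estrogen receptor alpha, fell by 1.16 on the log2 scale, from 36.5 ± 3.96 to 15.8 ± 1.24. Induced targets had 7 of 35 higher, 10 when adjusted over the list alone, with OLFM1 at 1.37, AREG at 1.24, RERG at 1.06 and TFF1, a secreted trefoil peptide gene, at 0.76 (camera adjusted p = 3.43e-07, and adjusted p = 0.0244 with an estimated correlation). Ribosome biogenesis genes had 12 of 30 higher, 25 when adjusted over the list alone (camera adjusted p = 9.33e-21, and adjusted p = 0.00893 with an estimated correlation). Heat shock genes had 3 of 12 higher, HSPA8, HSP90AB1 and DNAJA1, and 7 when adjusted over the list alone (camera adjusted p = 4.60e-07, and adjusted p = 0.0277 with an estimated correlation). The 3 aryl hydrocarbon receptor targets that had risen at 3 h passed at 6 h too (camera adjusted p = 2.53e-05, and adjusted p = 0.0474 with an estimated correlation). In single cells of 6 h this list was not higher than at 0 h, with a median of -0.27 and 2 of 6 members higher. In all, 421 genes passed at 6 h, 278 higher and 143 lower. Leaving out any 1 library lowered that count to between 53 and 203, and the balance of directions turned without replicate 1 of 0 h (38 higher and 42 lower) and without replicate 2 (29 and 39). Fitting only the 4 libraries of 0 and 6 h gave 11.

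**Figure D2:**
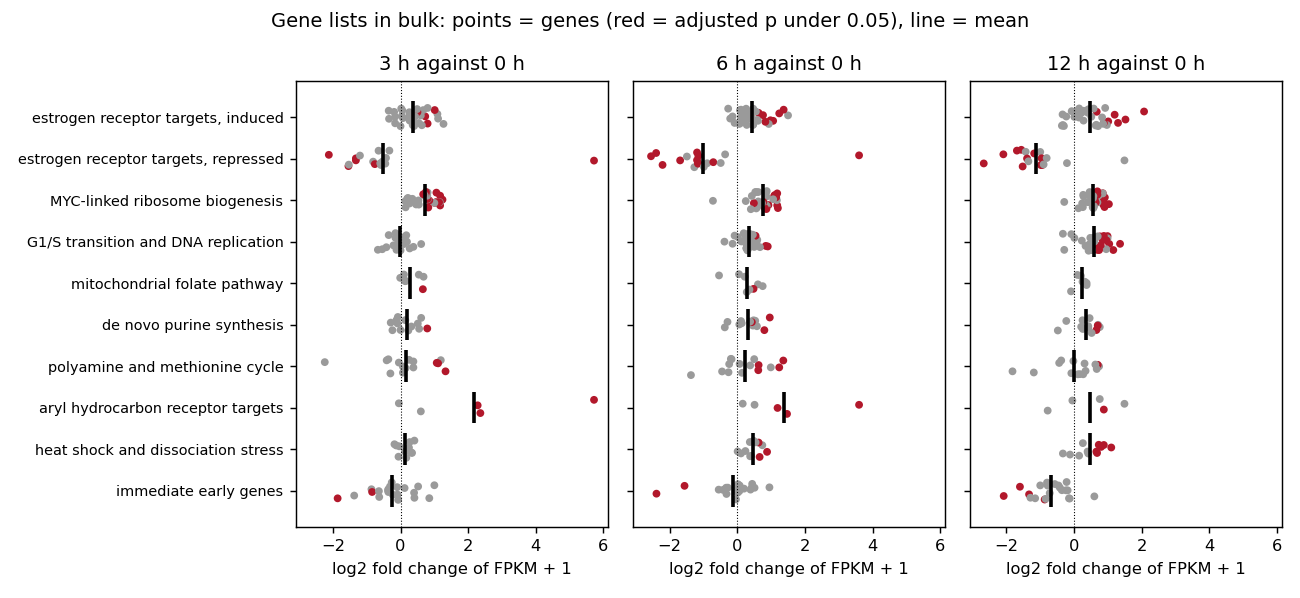
Log2 fold change of FPKM + 1 against 0 h in bulk (horizontal axis) for the tested members of 10 gene lists (vertical axis) at 3, 6 and 12 h. Points are genes, red where the limma adjusted p was under 0.05, and lines mark list means. The mean of the MYC-linked ribosome biogenesis list was 0.73 at 3 h, 0.77 at 6 h and 0.56 at 12 h, and that of the G1/S list was -0.02, 0.33 and 0.60.

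The comparison at 12 h covered the longest exposure. GREB1, an estrogen-induced growth regulator, rose from an FPKM of 19.8 ± 2.24 (SD, n = 2) to 58.8 ± 4.94 (SD, n = 2), a log2 fold change of 1.52 (SE 0.14), and TFF1 from 5661 ± 120 to 11380 ± 877. CXCL12, a chemokine gene, was higher by 2.07, OAS1, an interferon-inducible gene, by 1.74, IGSF1 by 1.6 and FABP5 by 2.25. CLEC3A was lower by 3.00 on the log2 scale (5.69 ± 1.71), PSCA changed by -2.67 and CALCOCO1 by -2.31. The histone gene HIST1H3D changed by -2.21, but its reads may be shared with near-identical copies. The symbol UQCR11 stands for 2 entries of the table: one had means of 0.00201 at 0 h and 15.5 ± 9.25 at 12 h and passed, while the other had 165 ± 5.25 and 140 ± 8.98 and did not (limma adjusted p = 0.308), and reads may be shared between them. SNORD68 and RNU1-70P were listed at 0 in both 0 h libraries, AP000758.1 in both 12 h libraries, and SNORA73B rose by 2.72. The loci RP11-112J1.1, CTB-167G5.5 and RP11-719K4.3 changed by -3.51, -2.22 and -2.12. Without 1 library the calls of FABP5 and CLEC3A held in each of the 8 fits, while those of CXCL12, IGSF1 and RP11-719K4.3 ended in 8, of SNORA73B in 7, of CALCOCO1, HIST1H3D, UQCR11 and CTB-167G5.5 in 6, of OAS1 and RP11-112J1.1 in 4, of TFF1 in 3 and of GREB1 and PSCA in 2. PGR, the progesterone receptor gene, had means of 1.53 ± 0.742 and 3.05 ± 0.0378 (limma adjusted p = 0.273), and neither MYC (adjusted p = 0.308) nor CCND1 (adjusted p = 0.452) passed.

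Genes of the G1/S transition and DNA replication had 13 of 31 members higher at 12 h and none lower, 21 higher when adjusted over the list alone. MCM10 rose by 1.36, DTL by 1.16, CDC45 by 1.04, CCNE2 by 0.99 and PCNA by 0.68 (camera adjusted p = 1.21e-14, and adjusted p = 0.0292 with an estimated correlation). At 6 h the list had 3 members higher and at 3 h none, where 0 also passed when adjusted over the list alone. Induced estrogen receptor targets had 7 of 35 higher at 12 h, 10 when adjusted over the list alone (camera adjusted p = 1.66e-07, and adjusted p = 0.0212 with an estimated correlation). Repressed targets had 10 of 17 lower, 15 lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.50e-13, and adjusted p = 0.0140 with an estimated correlation). Ribosome biogenesis had 10 of 30 higher, 18 when adjusted over the list alone (camera adjusted p = 1.56e-15, and adjusted p = 0.0140 with an estimated correlation). Heat shock had 6 of 12 higher by either adjustment, HSPA8 by 1.10 and HSPD1 by 0.88 (camera adjusted p = 1.56e-06, and adjusted p = 0.0278 with an estimated correlation). Immediate early genes, which answer growth factors and stress within minutes, had 4 of 21 lower at 12 h, CTGF (-2.08), BTG2 (-1.6), DUSP1 (-1.33) and FOS (-0.87), and 8 when adjusted over the list alone (camera adjusted p = 1.63e-07, and adjusted p = 0.0212 with an estimated correlation). In all, 414 genes passed, 231 higher and 183 lower, and 317 passed the test of any effect of time. Leaving out any 1 library lowered the count at 12 h to between 45 and 153, and the balance of directions turned without replicate 1 of 0 h (11 higher and 48 lower) and without replicate 2 (7 and 38). Both 0 h libraries carry one name prefix and both 12 h libraries another, while 3 h and 6 h have 1 of each, and with the prefix as a covariate 8 genes passed at 12 h, 94 at 6 h and 68 at 3 h.

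Later times were also compared with each other. Between 6 and 12 h, SAT1, which acetylates spermidine and spermine for their breakdown, fell from 247 ± 29.7 (SD, n = 2) to 114 ± 4.35 (SD, n = 2), a log2 fold change of -1.11 (SE 0.11, limma adjusted p = 0.0385). It was the only protein-coding gene among the 5 that passed; the others were SNORD68, RNU6-450P, SNORA45 and RP11-162J8.3, each listed at 0 in both libraries of 1 of these times. Immediate early genes had no member past the threshold between 6 and 12 h and 5 lower when adjusted over the list alone (mean -0.56, camera adjusted p = 1.22e-09, and adjusted p = 0.0463 with an estimated correlation). Between 3 and 12 h, a comparison added after the data were examined, 65 genes passed, 32 higher and 33 lower. CYP1A1 fell by 4.23 on the log2 scale and CYP1B1 by 1.40, while TFF1 rose by 0.66 and OAS1 by 1.67. The call of TFF1 ended in each of the 8 fits without 1 library, and those fits kept few of the 65 calls. G1/S genes had 8 of 31 higher, 23 when adjusted over the list alone (camera adjusted p = 4.98e-19, and adjusted p = 0.0452 with an estimated correlation). G2/M genes had 2 of 30 higher, 20 when adjusted over the list alone (camera adjusted p = 6.31e-16, and adjusted p = 0.0452 with an estimated correlation). Between 3 and 6 h, 7 genes passed, of which CYP1B1 (-1.09) was the only protein-coding one. Leaving out 1 library gave 5 to 47 genes for 12 against 6 h, 5 to 44 for 12 against 3 h and 8 to 41 for 6 against 3 h. Without replicate 1 or 2 of 3 h the genes for 12 against 3 h were 6 higher and 38 lower or 3 and 30, and without replicate 1 or 2 of 12 h they were 32 and 9 or 31 and 8. The balance moved likewise for 12 against 6 h (1 higher and 34 lower without replicate 1 of 6 h, 30 and 17 without replicate 2 of 12 h) and 6 against 3 h (6 and 35 without replicate 1 of 3 h, 34 and 4 without replicate 1 of 6 h), and SAT1 no longer passed against 6 h in 7 of the 8 such fits.

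The series title names the mitochondrial folate pathway, purine synthesis and polyamine synthesis. In bulk, MTHFD2, a mitochondrial folate dehydrogenase and cyclohydrolase gene, rose from 183 ± 5.30 (SD, n = 2) to 291 ± 7.92 (SD, n = 2) at 3 h (log2 fold change 0.66, SE 0.09) and was higher by 0.48 at 6 h. It was 230 ± 7.30 at 12 h (limma adjusted p = 0.108). SHMT2, the mitochondrial serine hydroxymethyltransferase gene, had means of 65.3 ± 6.70 at 0 h and 84.3 ± 4.90 at 12 h, a change that did not pass (adjusted p = 0.129), nor did MTHFD1L at any time. The list of 8 tested genes had 1 member higher at 3 h, 1 at 6 h and 0 at 12 h, and 1, 1 and 2 when adjusted over the list alone. Its camera adjusted p was 0.0374, 0.0126 and 0.0328, and none held with an estimated correlation (adjusted p = 0.202, 0.126 and 0.179). By fry, which makes no comparison with other genes, adjusted p was 0.0498, 0.0344 and 0.0711. Leaving out replicate 2 of 0 h ended the camera call at 12 h (adjusted p = 0.212), as did leaving out replicate 2 of 12 h (adjusted p = 0.0812).

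For purine synthesis, PPAT, its first committed enzyme, rose by 0.79 at 3 h, 0.80 at 6 h and 0.70 at 12 h, and PAICS by 0.43 at 6 h and 0.66 at 12 h. ADSL rose by 0.96 at 6 h, and GART and ATIC did not pass at any time. Of 13 members 1, 3 and 2 rose at 3, 6 and 12 h, and 2, 5 and 6 when adjusted over the list alone. Camera adjusted p was 0.0799, 8.66e-04 and 6.29e-05, and none held with an estimated correlation (adjusted p = 0.380, 0.126 and 0.0809). By fry, without comparison with other genes, adjusted p was 0.076, 0.0125 and 0.00741. For polyamine synthesis, ODC1, its rate-limiting enzyme, rose from 5.12 ± 1.86 to 14.1 ± 1.85 at 3 h and was higher by 1.36 at 6 h. AMD1, which makes the aminopropyl donor, rose by 1.11, 1.24 and 0.70 at the 3 times, and MAT2A by 1.07 and 0.62 at 3 and 6 h. SRM, with changes of 1.19, 0.99 and 0.74, did not pass (adjusted p = 0.0602, 0.0773 and 0.148). Of 15 members 3, 4 and 1 rose and none fell. When adjusted over the list alone, 6 rose and 2 fell at 3 h, 7 rose at 6 h, and 6 rose and 4 fell at 12 h. Camera adjusted p was 0.0469, 0.0116 and 0.105, and adjusted p with an estimated correlation was 0.202, 0.126 and 0.232. Fry adjusted p was 0.00661, 0.00632 and 0.0475. The calls of ODC1 and PPAT ended in each of the 8 fits that left out 1 library, as did that of MTHFD2 at 6 h, while MTHFD2 at 3 h lost its call in 6 of them and AMD1 at 3 h in 5, without a change of direction. At 12 h the polyamine list's mean was 0.00 and its median 0.17. SAT1 changed by -0.78 at 12 h, alone among 6 genes of polyamine catabolism and antizymes (camera adjusted p = 0.568).

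**Figure D3:**
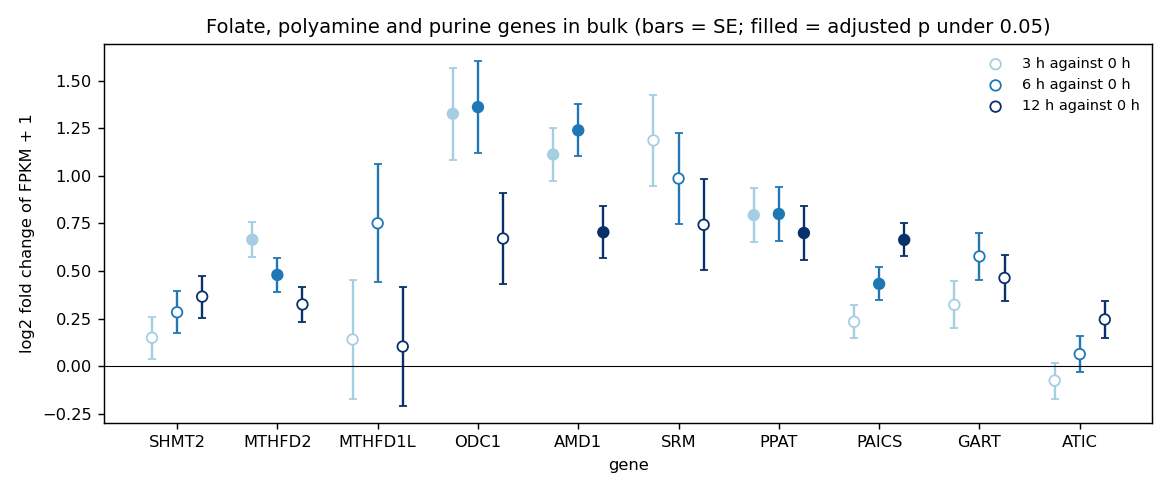
Log2 fold change of FPKM + 1 against 0 h (vertical axis) for 10 folate, polyamine and purine genes (horizontal axis) in bulk at 3, 6 and 12 h, 2 libraries per time. Bars are limma standard errors and filled symbols have an adjusted p under 0.05. AMD1 passes at all 3 times and SHMT2 at none.

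Single cells were described by level alone: no culture is named, so each time counted as 1 sample and no test was made between times. TFF1 had a mean FPKM of 2870 in cells of 0 h, 6732 at 3 h, 8584 at 6 h and 12500 at 12 h, and was at an FPKM of 1 or more in every one of the 85 cells. For GREB1 the mean was 17.1, 26.9, 57.0 and 60.7 and the median 3.20, 25.8, 31.0 and 57.5. PGR was at an FPKM of 1 or more in 3 of 21 cells at 0 h (14.3%, 95% exact binomial interval 3.0 to 36.3%) and in 6 of 21 at 3 h (28.6%, 11.3 to 52.2%). At 6 h it was so in 12 of 19 (63.2%, 38.4 to 83.7%) and at 12 h in 16 of 24 (66.7%, 44.7 to 84.4%). CYP1A1 was so in 2 of 21 cells at 0 h, 12 of 21 at 3 h (57.1%, 34 to 78.2%), 1 of 19 at 6 h and 1 of 24 at 12 h. SLC7A5 was so in 8 of 21 cells at 0 h (38.1%, 18.1 to 61.6%) and all 21 at 3 h. All intervals cover counting error only, and the dye changed colour between 3 and 6 h.

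**Figure D4:**
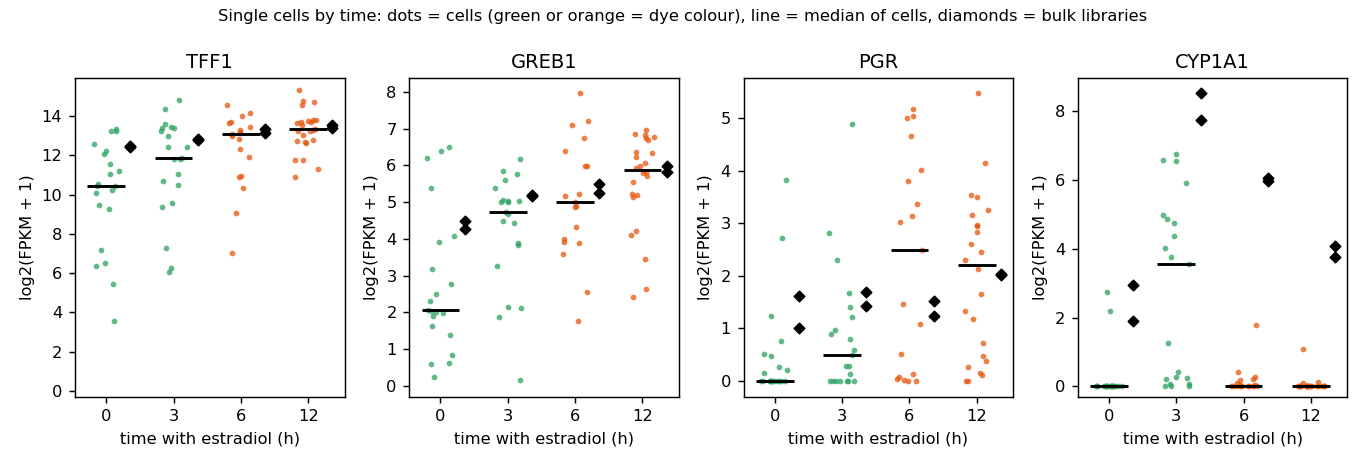
Log2(FPKM + 1) of 4 genes (vertical axis) in each single cell by hours with estradiol (horizontal axis). Dots are cells, coloured by their dye, lines are medians and diamonds the 2 bulk libraries of each time. Median TFF1 was 1402 FPKM at 0 h and 10190 at 12 h, and CYP1A1 was at 1 or more in 12 of 21 cells at 3 h.

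Among lists in cells, the median of 34 estrogen-induced genes was 0.63, 1.31 and 1.09 above 0 h at 3, 6 and 12 h on the log2 scale, at percentile 100 of 10000 random lists matched on mean level each time. Repressed genes had medians of -0.86, -0.29 and -0.89, at percentiles 0.1, 14.7 and 0.0. Members of a list can move together, which the random lists do not copy, so an extreme percentile is no test between times. The ribosome biogenesis list had 0.65, 0.34 and 0.14, at percentiles 100, 98.8 and 95.3. G1/S genes were at 0.75 at 12 h, with 28 of 30 members higher than at 0 h (percentile 100), and at 0.71 in 12 h against 6 h cells, which share a dye colour. G2/M genes had medians of 0.10, -0.89 and 0.24, at percentiles 79.0, 0.0 and 97.3. The mitochondrial folate list had 0.25, 0.23 and 0.57 (percentiles 84.2, 80.8 and 98.9), with MTHFD2 at a mean of 56.7, 81.6, 125.7 and 107 by time and SHMT2 at 25.9, 36.2, 31.8 and 37.4. Purine synthesis had medians of 0.01, -0.13 and 0.09 (percentiles 57.6, 26.1 and 77.2) and the polyamine and methionine list 0.22, 0.41 and 0.21 (percentiles 87.8, 97.1 and 89.8). ODC1 had a mean of 4.92 at 0 h and 15.7 at 12 h, and was at an FPKM of 1 or more in 7 of 21 cells (33.3%, 14.6 to 57.0%) and 17 of 24 (70.8%, 48.9 to 87.4%). Cells of 3 and 6 h hold other library-number positions than those of 12 h and 20 of the 21 of 0 h, so differences across these positions, ribosome biogenesis at 3 and 6 h among them, need not come from time alone.

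By the size rule, the genes with the lowest 12 h to 0 h ratios in cells included 3 aldo-keto reductase genes. AKR1C2 had a mean of 566 at 0 h, 278 at 3 h, 35.7 at 6 h and 32.3 at 12 h. In bulk it was 41.8, 39.4, 44.1 and 44.5, and its bulk log2 fold change at 12 h was 0.10 (SE 0.13, limma adjusted p = 0.754). AKR1C3 went from a cell mean of 98.2 to 4.86, and fell in bulk too (-1.70, SE 0.24, limma adjusted p = 0.0189), a call that ended in 7 of the 8 fits without 1 library, with adjusted p up to 0.145. AKR1C1, from 29.3 to 0.965, is close in sequence to both, so that their levels are uncertain relative to one another. PTGR1, a prostaglandin reductase gene, went from 362 to 54.3 and GPX2, a glutathione peroxidase gene, from 119 to 11.7, with bulk changes of -0.03 and 0.20 that did not pass. Also by this rule, the mean of CHD3 was 84.3 at 0 h and 8.59 at 12 h, of PIK3C3 43.5 and 5.75, and of KRT86 43.1 and 5.84. Among the 8 highest ratios, ORC1, a subunit of the origin recognition complex, had a mean of 0.554 at 0 h and 16.9 at 12 h. TAMM41 had 4.14 and 36.7, AGR3 7.93 and 60.6, TST 2.13 and 20.9, TMEM67 0.775 and 12.8, METTL10 1.14 and 14.9, and DIS3L 1.26 and 15.2. RNU6-33P, a small RNA gene, had 20.3 and 162, but its median went the other way, from 15.1 to 4.72, as did its bulk change (-1.295). None of these 8 passed in bulk at 12 h.

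**Figure D5:**
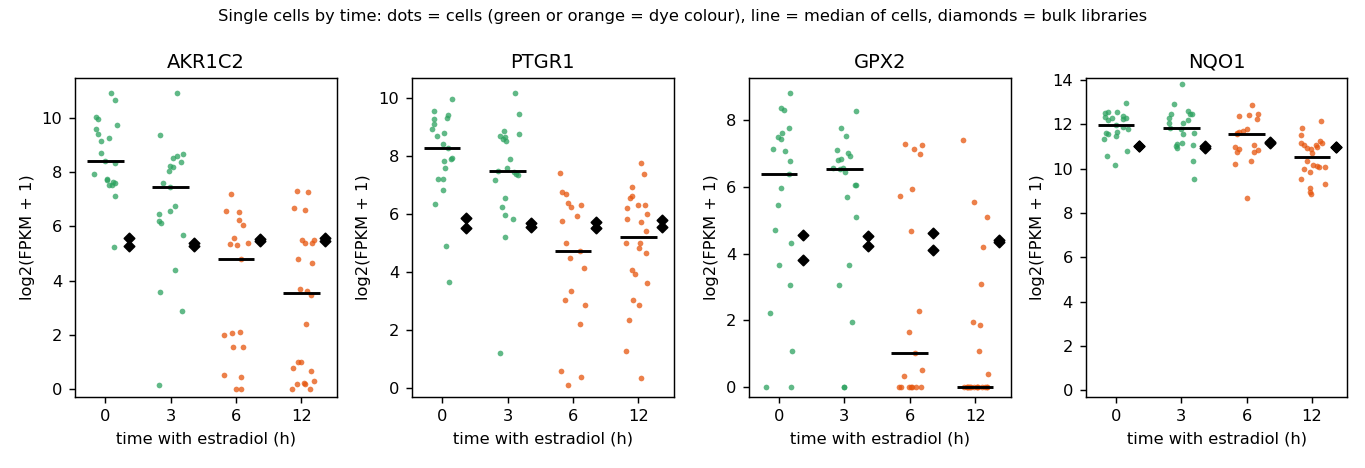
Log2(FPKM + 1) of AKR1C2, PTGR1, GPX2 and NQO1 (vertical axis) in each single cell by hours with estradiol (horizontal axis), with dots coloured by dye, lines at the medians and diamonds for the 2 bulk libraries of each time. Median AKR1C2 was 342 FPKM in cells at 0 h and 10.7 at 12 h.

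Cell and bulk changes were set side by side over 12116 genes measured in both. Over all of them Pearson's r between bulk and cell changes was 0.079, 0.075 and 0.131 at 3, 6 and 12 h (Spearman's rho 0.146, 0.121 and 0.162). These are correlations across genes, which are not independent replicates. Over the genes called in bulk, Pearson's r was 0.572 at 3 h (249 genes), 0.336 at 6 h (414 genes) and 0.524 at 12 h (407 genes, and Spearman's rho 0.452, 0.448 and 0.566). The direction matched for 82.7%, 75.4% and 77.4% of called genes and for 54.9%, 52.8% and 55.2% of genes not called. Immediate early genes had a median in cells of 0.34, 0.77 and 0.76 above 0 h (percentiles 97.0, 100 and 100), and a median in bulk of -0.26, 0.01 and -0.72, of which the camera call at 12 h alone passed. Between the times of the 2 dye colours the list differed by 0.42 (percentile 99.9), and between 12 and 6 h by -0.09 (percentile 36.7). The 0.34 at 3 h came within the green dye, before the colour changed. Colour and time changed together at 6 and 12 h, so they cannot be told apart there. FOS had a cell mean of 155 at 0 h and 394 at 12 h, and a bulk mean of 228 ± 5.77 and 125 ± 9.25 (SD, n = 2).

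Luminal markers had 1, 1 and 2 of 14 members lower in bulk at 3, 6 and 12 h, ELF3 each time and GATA3 (-0.67) at 12 h, and 2, 3 and 5 when adjusted over the list alone. Camera adjusted p was 0.0374, 0.00983 and 0.00537, and none held with an estimated correlation (adjusted p = 0.190, 0.126 and 0.0773). Basal markers had none of 4 past the threshold at any time (camera adjusted p = 0.304, 0.452 and 0.457), with 1 higher at 3 h, 1 higher and 1 lower at 6 h and 1 lower at 12 h when adjusted over the list alone. Only 2 members each of the fibroblast list (FN1 and VIM) and of the blood and immune list (the haemoglobin genes HBA1 and HBA2) reached the level needed for a test in bulk, so neither list was tested there. In cells the fibroblast list again had too few measured members, and the blood and immune list had 3, HBA1, HBA2 and the lysozyme gene LYZ. Their median of 0.33, 1.86 and 1.26 at 3, 6 and 12 h (percentiles 71.9, 98.5 and 94.9) is the value of HBA2, with LYZ at -0.83, -0.81 and -0.48, and reads may be shared between HBA1 and HBA2.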

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

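The tests of explanations in the last 3 paragraphs and the comparisons with 3 h were chosen after the data were seen, while the comparison of 12 with 6 h and the fits without 1 library were planned. Each change named in the next 2 paragraphs is a direct limma comparison of later times, which tests whether the changes against 0 h differ between them.

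CYP1A1 was lower at 12 h than at 3 h by a log2 fold change of -4.23 (SE 0.37), and CYP1B1 by -1.40 (SE 0.10) at 12 h and -1.09 (SE 0.10) at 6 h. CLEC3A was lower at 12 h than at 3 h (-1.50, SE 0.22), as was SAT1 (-0.84, SE 0.11), which was also lower at 12 h than at 6 h (-1.11, SE 0.11). OAS1 was higher at 12 h than at 3 h (1.67, SE 0.20), as was TFF1 (0.66, SE 0.09). The calls of SAT1 and TFF1 between 3 and 12 h ended in each of the 8 fits without 1 library. That of SAT1 between 6 and 12 h ended in 7 of them. These fits kept few of the calls between 3 and 12 h. Those of CYP1A1, CYP1B1, CLEC3A and OAS1 between these times should thus not be read as having held in each fit.

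A further 7 genes that differed between later times were listed at 0, or next to it, in both libraries of one of the times, so that the fitted values are no measure of size. SNORD14A, Y_RNA and SNORA27 had fitted values of -9.57, -6.81 and -6.02 both at 6 h and at 12 h against 3 h. RNU6-450P, SNORA45 and RP11-162J8.3 had 6.78, 4.83 and 4.91 at 6 h against 3 h and -6.78, -4.83 and -4.91 at 12 h against 6 h. SNORD68 had 9.38 at 12 h against both 3 h and 6 h.

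Genes of the NRF2 and glutathione list had medians in single cells of -0.51 at 6 h (15 of 19 lower) and -0.86 at 12 h (14 of 19 lower), and 8 of its 19 members (AKR1B10, AKR1C1, AKR1C2, AKR1C3, G6PD, ME1, NQO1 and SLC7A11) had a log2 ratio of -1 or less at 12 h. A response to estradiol is argued against for the 7 members other than AKR1C3. The median change of these 7 at 12 h was 0.31 in bulk (range -0.49 to 1.18) and -2.30 in cells. AKR1C3 fell in bulk as well (-1.70). The -2.30 is biased by the choice of low ratios, but over all 19 members the medians were 0.16 in bulk and -0.86 in cells. AKR1B10, AKR1C1 and SLC7A11 were near the floor in bulk, with means of 1.09, 3.31 and 0.465 at 0 h. All 8 had a higher mean in cells than in bulk at 0 h already (AKR1C2 566 and 41.8, NQO1 4127 and 2070). At 12 h this held only for ME1 and SLC7A11. Counted in blocks of 8 library numbers, 3 and 6 h cells hold the last 4 positions and 12 h and 20 of 21 0 h cells the first 4, and these 8 members were lower at 6 h than at 3 h (median -1.24, and -0.71 over all 19), which a difference between positions alone would not produce; this test replaced, once it had been seen, a comparison between the positions (median -1.02). Dye colour may account for part of it and stays open: over all 19 members the median between colours was -0.79, against -0.19 between 3 and 0 h and -0.14 between 12 and 6 h within a colour. Over the 8 members these medians were -2.25, -1.12 and -0.06. They were chosen for low ratios of 12 h to 0 h, which favours both a difference between colours and a fall from 0 to 3 h. The -1.12 within the green dye is thus biased by that choice. In cells colour and time changed together, and the staining of each bulk library is not given. The bulk values above bear on a response to estradiol but do not test colour itself.

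Of 5 tested aryl hydrocarbon receptor targets 3 were higher in bulk at 3 h (camera adjusted p = 2.14e-05, and adjusted p = 0.0546 with an estimated correlation). One library did not carry it, as the lowest change of CYP1A1, CYP1B1 and TIPARP over the fits without 1 library was 1.98. Dye colour was shared by 0 and 3 h cells, in which the same genes had a median log2 ratio of 1.46 at 3 h. This argues against colour for the rise of these 3 genes in cells. The 6 members of the list measured in cells had a median of 0.40 (percentile 91.9). Cells of 0 and 3 h mostly differ in library-number position, and the staining of each bulk library is not given, so colour in bulk was not tested. Whether estradiol, its vehicle or the handling of the medium gave the rise stays open, since there is no vehicle library at 3 h; the list was lower at 12 h than at 3 h by a mean of -1.72, which each of these could produce.

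Small RNA genes had the largest fitted changes in bulk. Among their 285 tested genes, 22.7% of pairs of libraries of one time (259 of 1140) held 0 in one library and an FPKM of at least 10 in the other, against 0 of 41824 pairs of protein-coding genes. Estimates for short genes that switch between 0 and high values are a candidate explanation. A response to estradiol stays open: of the 16 called changes 12 could be measured in cells, and 58.3% of these (7 of 12) had the same direction there.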

How the results depend on the processing

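The fits with the name prefix and without small RNA genes were chosen after the data were seen. Genes past the threshold at 3, 6 and 12 h against 0 h (256, 421 and 414) numbered 165, 265 and 236 without a filter on low values, 64, 15 and 15 without trend, 68, 94 and 8 with the prefix, and 4, 11 and 1 with only the libraries of both times, a fit with fewer samples. The counts were within 1.5 times the reported ones with a pseudocount of 0.1, a mean FPKM of at least 5, both scalings and without small RNA genes. Leaving out 1 library gave 45 to 107, 53 to 203 and 45 to 153, where the lone library left at a time is assumed to vary like the others. For 12 against 6 h (5) the count was 3 with a pseudocount of 0.1, 2 without a filter, 2 without small RNA genes, 1 with only both times and 5 to 47 without 1 library. For 12 against 3 h (65) it was 37 without a filter, 146 at a mean of at least 5, 5 without trend, 13 with the prefix, 0 by limma with only both times (1814 at an unadjusted p under 0.05), and 5 to 44 without 1 library. For 6 against 3 h (7) it was 4 with a pseudocount of 0.1, 15 without a filter, 4 at a mean of at least 5, 2 without small RNA genes, 0 by limma with only both times (1117 at an unadjusted p under 0.05) and 8 to 41 without 1 library. For any effect of time (317) it was 182, 542, 21 and 23 without a filter, at a mean of at least 5, without trend and with the prefix, and 47 to 115 without 1 library. Apart from the fits with fewer genes or samples, the cause was not tested.

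With the 10k or 100k label as a block the counts were 163 at 3 h, 12 for 12 against 3 h and 150 for any effect of time, with 310, 339, 4 and 6 for 6 and 12 h against 0 h, 12 against 6 h and 6 against 3 h. The 6 correlations between times of a library's deviation from its time's mean lay between -0.013 and 0.051, so the libraries share a label and no measured pairing.

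Lists past the threshold at 12 h numbered 15, 6 with an estimated correlation and 14 to 16 without 1 library. The mitochondrial folate list at 12 h (camera adjusted p = 0.0328) had 0.0789 at a mean of at least 5, 0.0887 with quantile normalization, 0.179 with an estimated correlation and 0.00439 to 0.212 without 1 library. Purine synthesis had 0.0809 with an estimated correlation and 5.46e-06 to 0.00332 without 1 library. The polyamine list (0.105) had 0.0343 without a filter, 0.0308 at a mean of at least 5 and 0.0850 to 0.266 without 1 library. Induced and repressed estrogen receptor lists kept their calls at 12 h without 1 library, at 4e-07 to 6.08e-06 and 1.08e-12 to 1.38e-10.

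Of 146 calls of named genes against 0 h, 25 held without any 1 library (CYP1A1, CYP1B1, SLC7A5 and DDX21 at 3 h and FABP5, HSPA8 and CLEC3A at 12 h among them) and 35 ended without each one; none reversed. The 25 also include loci listed at 0, or next to it, in both libraries of a time. These were AP000758.1 at 3, 6 and 12 h, SNORD14A, SNORA27 and Y_RNA at 3 h, RNU6-450P, SNORA45 and RP11-162J8.3 at 6 h and SNORD68 at 12 h. Holding in these fits thus does not by itself vouch for a call. The calls that ended were 100 with the prefix, 144 with only both times, 109 without trend, 58 without a filter, 26 with the block, 5 with quantile normalization and 3 with a pseudocount of 0.1. In cells 413 values stayed, 19 moved and 1 reversed: the basal list at 6 h (-0.79) was 0.016 with the mean of log2 values. The alternative without cells of low gene number (under 0.5 of the median) was not run, as it removed 0 cells. Depth limits what can be said of low values, and is unknown.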

Other observations

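In bulk, neutral amino acid transporters moved apart. Beside SLC7A5 and SLC3A2, which rose, SLC38A2 changed by -0.86, -0.73 and -0.42 at 3, 6 and 12 h and SLC38A1 by -0.71 and -0.75 at 3 and 6 h. Of the 8 tested genes of serine synthesis and neutral amino acid transport, 1 rose and 2 fell at 3 h, 2 and 2 at 6 h and 1 and 1 at 12 h (4 and 2, 5 and 2, and 2 and 2 when adjusted over the list alone). Camera adjusted p was 0.304, 0.0492 and 0.172, and adjusted p with an estimated correlation 0.531, 0.243 and 0.381. ASNS, the asparagine synthetase gene, rose at 3 h (0.76) and 6 h (0.88), alone among 12 genes of the integrated stress response, and 4, 1 and 0 rose at 3, 6 and 12 h when adjusted over the list alone (camera adjusted p = 0.0222, 0.506 and 0.151, and adjusted p = 0.186, 0.540 and 0.232 with an estimated correlation). That list was lower at 12 h than at 3 h (mean -0.60, camera adjusted p = 1.50e-04, and adjusted p = 0.0486 with an estimated correlation), with 0 members past the limma threshold and 7 lower when adjusted over the list alone.

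NME1, a nucleoside diphosphate kinase gene, rose by 0.73, 0.97 and 1.05 at 3, 6 and 12 h, UMPS by 0.73 and 0.64 at 3 and 6 h and CTPS1 by 0.99 at 6 h, so that 2, 3 and 1 of 14 pyrimidine and deoxynucleotide genes rose (3, 4 and 6 when adjusted over the list alone). Camera adjusted p was 0.720, 0.00851 and 1.23e-04, and adjusted p with an estimated correlation 0.843, 0.126 and 0.0699. Of 10 cytosolic folate genes MTRR rose at 3 h (0.94) and MTHFD1 at 12 h (0.72), and 1, 0 and 1 when adjusted over the list alone (camera adjusted p = 0.273, 0.108 and 2.43e-04, and adjusted p = 0.380, 0.203 and 0.0519 with an estimated correlation). LDHA, the lactate dehydrogenase A gene, rose at 6 h (0.64) and 12 h (0.90) and PGK1 at 12 h (0.40), 2 of 17 glycolysis genes, with 0, 2 and 7 higher and 1 lower at 12 h when adjusted over the list alone (camera adjusted p = 0.713, 0.00851 and 3.68e-05, and adjusted p = 0.837, 0.157 and 0.0773 with an estimated correlation).

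CYCS, the cytochrome c gene, rose at 6 h (0.98) and 12 h (0.90) and NDUFA9 at 12 h (0.68), among 28 nuclear genes of oxidative phosphorylation, with 0, 1 and 5 when adjusted over the list alone (camera adjusted p = 0.720, 0.197 and 0.0234, and adjusted p = 0.864, 0.540 and 0.349 with an estimated correlation). None of the 13 mitochondrially encoded genes passed by limma at any time, and 0, 9 and 11 were lower when adjusted over the list alone (means -0.17, -0.38 and -0.41, camera adjusted p = 0.0134, 5.26e-07 and 4.78e-07, and adjusted p = 0.380, 0.126 and 0.130 with an estimated correlation). MSMO1 rose at 3 h (0.68) among 20 cholesterol synthesis genes, with 4, 0 and 0 when adjusted over the list alone (camera adjusted p = 0.0111, 0.00851 and 0.268, and adjusted p = 0.202, 0.180 and 0.496 with an estimated correlation). Of 19 NRF2 and glutathione genes, OSGIN1 (1.65), HMOX1 (1.46) and TXNRD1 (0.80) rose and AKR1C3 (-1.35) fell at 6 h, 3 rose at 3 h when adjusted over the list alone, 5 rose and 1 fell at 6 h and 1 rose and 1 fell at 12 h (camera adjusted p = 0.271, 0.00851 and 0.0634, and adjusted p = 0.396, 0.126 and 0.204 with an estimated correlation). For G2/M genes BUB1 fell at 3 h (-0.73) and CDC20 rose at 12 h (0.75), with 9 lower, 0 and 1 higher when adjusted over the list alone (camera adjusted p = 2.17e-08, 0.337 and 0.00587, and adjusted p = 0.103, 0.545 and 0.213 with an estimated correlation).

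In cells of the orange dye, medians at 12 h against 6 h were 0.71 for G1/S genes (percentile 100), 1.12 for G2/M genes (percentile 100), 0.51 for pyrimidine and deoxynucleotide genes (percentile 99.8), -0.42 for mitochondrially encoded genes (percentile 2.0) and -0.07 for estrogen-induced targets (percentile 51.0). These times share a colour but hold different library-number positions. So do 3 and 0 h cells, in the green dye, where position alone as the source would need falls of 0.71, 1.12 and 0.51 for the first 3 lists and a rise of 0.42 for mitochondrially encoded genes. Medians there were -0.07, 0.10, -0.60 and 0.19, with an SD over members of 0.847, 0.780, 0.990 and 0.108. This SD is a spread among genes of the same cells. How far the medians vary between samples of cells was not measured. For G2/M genes, 6 h cells, at the position of 3 h cells, had -0.89 against 0 h. Position alone would not give this, but without that variation no conclusion is drawn. All 13 mitochondrially encoded genes were higher at 3 h, the direction that position needs, so position stays open for them. G1/S genes had 0.75 at 12 h against 0 h, with 28 of 30 members higher (percentile 100), though 20 of the 21 0 h cells share the positions of 12 h cells. At 6 h, across positions, they had -0.06 against 0 h. Position alone would not give these values for G1/S genes, but here too the variation between samples of cells was not measured. A part of position, or the change of dye from 0 h, stays open. For pyrimidine and deoxynucleotide genes position stays open. These tests were chosen after the values were seen.

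The bulk libraries differed in small RNA. MT-TL1, a mitochondrial transfer RNA gene, had an FPKM of 281900 in replicate 1 of 0 h, 106600 in replicate 2 of 6 h and 118100 in replicate 1 of 12 h, and was listed at 0 in the other 5 libraries. Small RNA genes took 25.9%, 15.8% and 13.6% of all FPKM in these 3 libraries and 2.8% to 4.7% in the others. Correlation across genes between the 2 libraries of a time was 0.931 to 0.945, where genes are not independent replicates. A library's median correlation with libraries of other times was 0.923 to 0.936, and for replicate 1 of 3 h it was above that with its partner (0.936 and 0.931).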
